A study of Mus musculus with 16 samples.

How the data were processed

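Gene expression was measured on 16 microarrays with a pair of dyes, Cy3 and Cy5. Each array compared RNA of staggerer mice with RNA of control mice of the C57BL/6 strain, taken at postnatal days 5 to 6 from the same numbered litter. Per the labels' protocols, slices were made with a vibratome, the ventrobasal nucleus of the thalamus (VB) and the somatosensory cortex were dissected out and frozen, and total RNA was extracted on columns with DNase treatment. Per the same protocols, cortex RNA was reverse-transcribed with aminoallyl-dUTP and coupled to the dyes. VB RNA was amplified by template-switching PCR and labelled with dye-dUTP and Klenow fragment. Tissue and labelling method therefore coincide, and a difference between the tissues cannot be separated from a difference between the methods.

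The deposited values are normalized log ratios of the channels of an array, taken as log2. The base is not stated by the authors. The range, -16.975 to 21.653, does not settle it, since 76 values exceed a ratio that a 16-bit scanner allows in base 10 and 2 exceed it in base 2 as well, so folds rest on this assumption. The scanner, the background correction, the normalization method and the spot filter are not given in the sources used here. Channel intensities were not used here, so signal over background is unknown and no filter on low signal could be made. Each VB array held 17711 to 22207 values and each cortex array 19633 to 22580, of 24107 probes. The interquartile range of an array was 0.357 to 0.388 in VB and 0.384 to 0.554 in cortex. The highest correlation between any 2 arrays was 0.597.

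The labels name the dye of each RNA but not the numerator of the ratio. Each litter was hybridized on 2 arrays per tissue with the dyes swapped. A check planned for this question took, for each array, the deviation of its probes from the mean of the arrays with the same dye assignment, and correlated it with the deviation in the swapped array of the same litter. The mean rho was 0.0216 in VB, which ranked 2 of the 24 possible matchings of litters, and 0.0575 in cortex, which ranked 1 of 24. Columns already turned to run 1 way would give positive values and columns that follow the dyes negative ones, so by the plan they were used as deposited. The evidence is weak. In VB 2 of 4 litters had a positive and 2 a negative rho, and the mean was 0.00723 without litter 4. In cortex all 4 were positive, with a mean of 0.0340 without litter 4. Comparisons outside the plan leaned toward turned columns, though the receptor count in cortex did not pass. Opposite signs in the dye assignments were seen for 419 of 667 probes of nose and tongue receptors in VB (62.8%). Among all VB probes the share was 67.5%. In cortex 382 of 717 receptor probes had opposite signs (53.3%; exact binomial p = 0.0857), against 53.6% of all cortex probes. The difference between the assignments had r = 0.317 between the tissues. A genotype effect shared by the tissues could give that too, and probes are not independent replicates. That the columns follow the dyes is therefore not excluded, and every ratio rests on this choice. Read instead as Cy5 over Cy3, the columns would give other calls, which was added as an alternative after seeing the data. Whether the numerator is the mutant or the control RNA remains unsettled, so ratios are given as positive or negative and no gene is called higher or lower in the mutant.

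Probes were matched to mouse gene symbols through their accession (15685 probes), their symbol (2969) or a synonym (1695), and 20 symbols were kept as deposited. In all, 20369 probes had 1 symbol and 3738 had none. A probe counted in a litter where both arrays of its swapped pair had a value, and the pair was averaged, so the replicate was the litter, with 4 in each tissue. Probes of 1 symbol were averaged per gene, probes with no symbol remained features of their own, and features with a value in at least 3 of the 4 litters were tested.

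Each tissue was fitted with limma 3.58.1 in R 4.3.3, and a mean log2 ratio of 0 was tested with the two-sided moderated statistic of eBayes. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 over all features of the tissue. The difference between tissues was tested in limma as VB minus cortex over the 8 litter values. The labels number litters 1 to 4 in both tissues, so a fit with litter as a replicate block was run beside it. Over the genes with complete values, the correlations between the VB and the cortex ratios of the same litter were -0.003, -0.016, -0.012 and 0.031. The correlation across genes between the tissue means was set against all 64 regroupings made by changing the sign of whole litters.

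Gene lists, 30 in number, were tested with camera at an inter-gene correlation of 0.01 on genes with values in all 4 litters, with camera at an estimated correlation and with fry. The lists covered RORα and clock genes, RORα targets of Purkinje cells, thalamic nuclei, cortical layer 4, upper and deep cortical layers, barrel formation, axon guidance, synaptic adhesion, activity-regulated genes, glutamate and GABA receptors, ion channels, synaptic vesicles, neuronal maturation, immature neurons and the cell cycle. They also covered GABAergic neurons, oligodendrocytes, astrocytes, microglia, vascular cells, blood cells, choroid plexus and meninges, neighbouring brain regions, cholesterol synthesis, glucocorticoid response, antioxidant genes, thyroid-responsive genes, neighbours of Rora on its chromosome and sex-linked genes. In cortex the sex-linked list had too few complete members for camera, which left 29 lists there. Members were also tested with p adjusted over the list alone.

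The lists, the tests, the thresholds, the named genes and most alternatives were fixed before the data were examined. The named genes were Rora, the 10 most positive and the 10 most negative genes that passed with the same sign in all 4 litters, and up to 4 members with the smallest p of each list described. Where fewer than 3 passed in a direction, the 3 smallest p of that direction were added. For the difference between tissues they were the 5 largest each way. Other genes named are marked as chosen after their values were seen.

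The pipeline was tested on simulated data with the same missing values. With a log2 change of 0.5, limma recovered 96 of 100 changed genes in VB (96% of them, among 16066 features) and 49 of 100 in cortex (49%, among 16520), and with a change of 1 all 100 in each. For the difference between tissues, 47 of 144 genes (32.6%) were recovered at 0.5 and 146 of 151 (96.7%) at 1, among 12179. False calls were 11 of 207 in VB, 12 of 161 in cortex and 12 of 205 for the difference. With no change simulated, limma called 0 genes in VB, 1 in cortex and 0 for the difference. For the difference with litter as a replicate block, false calls were 22 of 226, and 2 with no change simulated. Camera found a simulated shift of -0.3 in the axon guidance list in both tissues (39 genes in VB, 32 in cortex) and no other list. The simulated dye effect cancelled in each swapped pair, and genes were simulated as independent. These counts therefore do not show the errors that a remaining dye effect or correlated genes would cause.

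Alternative settings were centring on the median, quantile normalization between arrays, arrays kept apart with a dye term and litter as a random effect, each dye assignment by itself, both tissues in 1 fit, robust eBayes, each probe by itself, stricter and looser rules on missing values, an adjusted p under 0.10, a fold of at least 1.5, and leaving out each litter. Added after seeing the data were the restriction to genes with the same sign in both dye assignments, a loess correction of the remaining dye effect with a span of 0.3, cameraPR on all genes tested, and columns read as Cy5 over Cy3. Tables and figures were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9, and block correlations with statmod 1.5.0.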

Results

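Staggerer mice carry a deletion in Rora, the gene of the nuclear receptor RORα. The arrays addressed the part RORα plays in the maturation of the thalamus and cortex during the first postnatal week, when axons of the VB, which relays touch from the whiskers, settle in layer 4 of the somatosensory cortex. Mutant and control RNA of 4 litters were compared in VB and in cortex, each litter on 2 arrays with the dyes swapped, which gave 16 arrays and 4 ratios per gene and tissue. The number of arrays limits the precision. After averaging the swapped pair, 16066 features (13407 gene symbols) were tested in VB and 16520 (13776 symbols) in cortex. The median SD between litters was 0.133 log2 units in VB and 0.208 in cortex. Since it is not known whether the mutant or the control RNA is the numerator, a positive ratio is not read as higher in the mutant, and all signs would swap together. Folds assume base 2, which is not stated. All ratios take the columns to run 1 way, as a check with weak support had it.

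The first comparison asked which transcripts differed between staggerer and control VB. The Rora probe had a log2 ratio of -0.13 ± 0.12 (SD, n = 4 litters; limma adjusted p = 0.554), negative in 3 of 4 litters, and did not pass. Its mean was 0.29 in the arrays with mutant RNA in Cy5 and -0.56 in those with control RNA in Cy5, and where the probe lies relative to the deleted part of the gene is unknown.

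Among the negative ratios in VB, Gja1, which encodes the astrocyte gap junction protein connexin 43, had a log2 ratio of -0.57 ± 0.11 (0.673-fold; SD, n = 4; limma adjusted p = 0.0086). Ednrb, the endothelin receptor B, stood at -0.72 ± 0.24 (0.607-fold, adjusted p = 0.0101). Ccnd3, the cell cycle gene of cyclin D3, had -1.21 ± 0.52 (0.432-fold), and Iltifb, a cytokine gene related to interleukin 22, had -1.43 ± 0.62 (0.370-fold), both with an adjusted p of 0.0101. Calb2, which encodes the calcium-binding protein calretinin, had -0.41 ± 0.09 (0.754-fold, adjusted p = 0.0348). Ado, a thiol dioxygenase, had -0.80 ± 0.13 (adjusted p = 0.000835). Ratios of -0.52 for the ubiquitin ligase gene Rnf182, -0.47 for the antiproliferative gene Btg1 and -0.47 for Sat1, an enzyme of polyamine breakdown, completed the named genes. All 9 had the same sign in all 4 litters and in both dye assignments. Each was smaller in size with mutant RNA in Cy5 than with control RNA in Cy5, such as Btg1 (-0.05 and -0.89), Gja1 (-0.16 and -0.98) and Ednrb (-0.16 and -1.28).

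Positive ratios passed for Slc24a5, an ion exchanger of pigment cells, at 0.86 ± 0.39 (1.82-fold; SD, n = 4; limma adjusted p = 0.0157). Iqsec1, an exchange factor for Arf GTPases at synapses, had 0.70 ± 0.34 (1.62-fold, adjusted p = 0.0301), and the ribosomal protein gene Rps4l had 0.67 ± 0.22 (1.59-fold, adjusted p = 0.0101). These 3 were positive in both dye assignments, but much smaller with mutant RNA in Cy5 than with control RNA in Cy5. The values were 0.13 and 1.59 for Slc24a5, 0.07 and 1.33 for Iqsec1, and 0.17 and 1.16 for Rps4l. The other 7 named genes were positive on average but negative in the arrays with mutant RNA in Cy5. They were Cep152, a centriole gene (2.82-fold; -0.21 with mutant RNA in Cy5 and 3.21 with control RNA in Cy5), Kif24, a kinesin of centrioles (mean log2 ratio 1.28; -0.04 and 2.59), Cited4 (1.39; -2.72 and 5.50), Arhgef40 (1.34; -3.24 and 5.93), Tcte3 (1.15; -0.97 and 3.27), Trim46 (0.62; -0.66 and 1.90) and the vomeronasal receptor gene Vmn1r219 (0.70; -0.99 and 2.40).

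**Figure D1:**
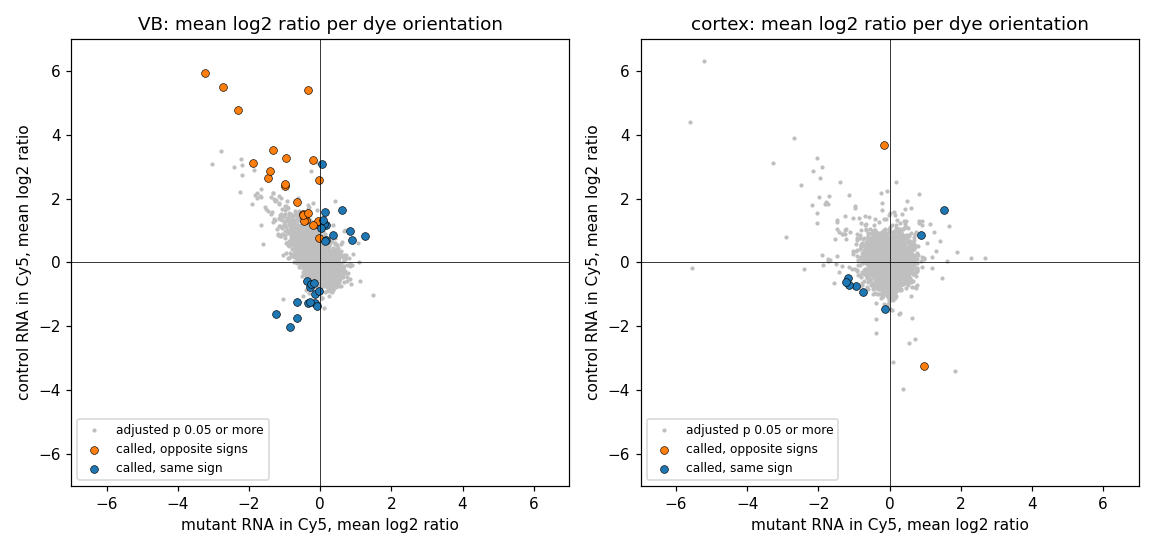
Mean log2 ratio of each gene in the arrays with mutant RNA in Cy5 against the arrays with control RNA in Cy5, for VB and for cortex, with called genes marked and 2 cortex genes outside the axes. Across genes the assignments had r = -0.593 in VB and -0.221 in cortex, and genes are not independent replicates.

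In all, 51 of 16066 features were called in VB, 37 with a positive and 14 with a negative ratio, and 1642 had an unadjusted p under 0.05. Of the 51, 27 had the same sign in both dye assignments (13 positive, 14 negative), against 32.5% of all features tested. The other 24 had opposite signs, all with a positive mean. For 49 of the 51 the ratio was larger in size with control RNA in Cy5. Quantile normalization left 19 calls (10 positive, 9 negative), of which 18 were among the 51, and ended those of 8 named genes. The log2 ratio became smaller for Arhgef40 (0.76), Tcte3 (0.68), Slc24a5 (0.69), Vmn1r219 (0.42), Iqsec1 (0.56) and Trim46 (0.42), and slightly larger in size for Btg1 (-0.52) and Calb2 (-0.43). Loess dye correction, added after seeing the data, ended the calls of the same 8 genes, with Arhgef40 at 0.26, and that of Cited4 at 0.43. Robust eBayes ended the calls of Iltifb, Ccnd3, Arhgef40 and Tcte3, 1 fit of both tissues ended those of Cited4, Tcte3, Ednrb and Sat1, and with values in at least 2 litters only Cep152, Cited4, Kif24 and Ado of the named genes passed. Without litter 2 there were 32 calls and without litter 4 there were 156, and leaving out any of litters 1, 2 and 3 ended the calls of Sat1, Calb2, Tcte3 and Trim46, litter 1 or 2 that of Rnf182, litter 2 or 3 that of Btg1, litter 1 that of Iqsec1 and litter 2 that of Slc24a5.

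Of 17 thalamic nucleus genes, 7 were positive and 10 negative, Calb2 passed, and 3 negative genes passed adjusted over the list alone. The others were the serotonin transporter gene Slc6a4 (-0.41, adjusted p over all features 0.0949) and the monoamine transporter gene Slc18a2 (-0.23, 0.216), both active for a time in developing thalamic neurons. Of 29 barrel formation genes, 17 were positive and 12 negative, 0 passed over all features by limma, and 1 negative gene, Slc6a4, passed adjusted over the list alone. Of 16 RORα and clock genes, 4 were positive and 12 negative, 0 passed over all features, and Nfil3, a repressor of clock output, passed adjusted over the list alone (-0.36 ± 0.12, adjusted p over all features 0.0738). Of 23 activity-regulated genes, 8 were positive and 15 negative, and Dusp6 (-0.55, adjusted p over all features 0.0636) and Klf4 (-0.33, 0.150) passed adjusted over the list alone. Id2, a RORα target list member and inhibitor of DNA binding, passed at -1.43 ± 0.83 (SD, n = 3; limma adjusted p = 0.0449). Marcksl1 among immature neuron genes (0.44 ± 0.06), Lrrc4c, a synaptic adhesion gene that binds netrin-G1 (0.60 ± 0.12, n = 3), and Arrdc2 among glucocorticoid response genes (0.46 ± 0.04) passed with positive ratios. Slc6a4, Slc18a2, Dusp6, Klf4 and Arrdc2 had opposite signs in the dye assignments. Of the lists of Marcksl1, Lrrc4c and Arrdc2, 2, 3 and 1 positive genes passed adjusted over the list alone. Larger ratios that did not pass were 1.16 ± 1.13 for the glutamate receptor gene Grm3 (adjusted p = 0.206), 0.83 ± 0.61 for the vesicle gene Rab3b (0.0957) and -1.10 ± 1.69 for the pericyte gene Rgs5 (0.456). Of 20 astrocyte genes, 10 were positive and 10 negative, and Gja1 was the member that passed, also adjusted over the list alone.

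No list as a whole was called in VB by camera (0 of 30; 0 at an unadjusted p under 0.05; lowest adjusted p 0.928), by camera with an estimated correlation (0), by fry (0) or by cameraPR (0). Mean log2 ratios were -0.053 for thalamic nuclei, -0.022 for barrel formation, -0.051 for RORα and clock genes, -0.20 for RORα targets of Purkinje cells and -0.0025 for the neighbours of Rora. Among neuronal lists they were -0.013 for cortical layer 4, -0.0056 for upper layers, 0.058 for deep layers, -0.014 for axon guidance, 0.031 for synaptic adhesion, -0.083 for activity-regulated genes, 0.056 for glutamate and GABA receptors, -0.0021 for ion channels, 0.049 for synaptic vesicles, -0.068 for neuronal maturation, 0.023 for immature neurons and -0.040 for GABAergic neurons. Lists of other cells had means of -0.0054 for astrocytes, -0.022 for oligodendrocytes, -0.013 for microglia, -0.076 for vascular cells, 0.0099 for blood cells, -0.047 for choroid plexus and meninges and 0.019 for neighbouring regions. The remaining means were 0.012 for the cell cycle, 0.0053 for cholesterol synthesis, -0.045 for glucocorticoid response, 0.011 for antioxidant genes, 0.015 for thyroid-responsive genes and 0.064 for sex-linked genes. Mean, median and camera direction differed in sign for 12 of the 30 lists.

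The second comparison asked the same of the somatosensory cortex, where VB axons end. The Rora probe had a log2 ratio of -0.45 ± 0.26 (SD, n = 3; limma adjusted p = 0.357), negative in 3 of 3 litters with a value and in both dye assignments (-0.58 and -0.32), and did not pass.

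Among the negative ratios in cortex, Gja1 had -0.93 ± 0.30 (0.524-fold; SD, n = 4; limma adjusted p = 0.0173) and was the single feature called in both tissues. Sema7a, a membrane-anchored semaphorin that guides axons, had -0.84 ± 0.19 (0.557-fold, adjusted p = 0.0173), and Hpca, the neuronal calcium sensor hippocalcin, had -0.82 ± 0.19 (0.565-fold, adjusted p = 0.0173). Sncb, which encodes the presynaptic protein β-synuclein, stood at -0.91 ± 0.35 (0.531-fold, adjusted p = 0.0248), and Cyria, a regulator of Rac1 and actin, at -0.83 ± 0.30 (0.562-fold, adjusted p = 0.0339). These 5 were negative in all 4 litters and in both dye assignments.

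Among the positive ratios in cortex, Smtn, the smooth muscle gene smoothelin, had 1.59 ± 0.35 (3.01-fold; SD, n = 3; limma adjusted p = 0.0027), with 1.53 and 1.66 in the dye assignments. Its call ended where the unpaired array of litter 4 was counted, with 0.99 (adjusted p = 0.611), with 0.95 in the arrays with mutant RNA in Cy5 (0.267) and with 1.29 when arrays were kept apart (0.0657). Over the alternatives that take the columns to run 1 way, the limma adjusted p ran from 4.7e-06 to 0.611. Rgs4, which dampens G protein signalling in neurons, had 0.87 ± 0.21 (1.83-fold; SD, n = 3; limma adjusted p = 0.0439). Stmn1, the microtubule destabilizer stathmin of growing neurons, had 1.77 ± 1.07 (3.40-fold, adjusted p = 0.0439), from -0.14 with mutant RNA in Cy5 and 3.68 with control RNA in Cy5. Samd14 had 0.69 ± 0.25 and did not pass (adjusted p = 0.0724).

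**Figure D2:**
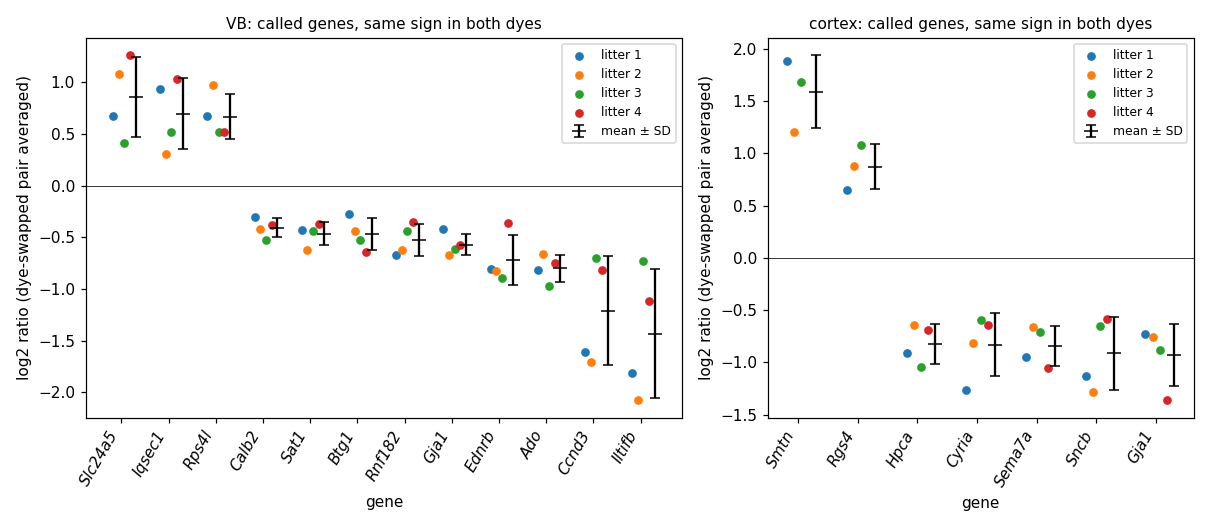
Log2 ratio of each litter, averaged over its dye-swapped pair (points), with mean and SD (bars), for the named genes called with the same sign in both dye assignments in VB and in cortex. Gja1 was negative in all 4 litters of both tissues, with means of -0.57 in VB and -0.93 in cortex.

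In all, 10 of 16520 features were called in cortex, 3 positive and 7 negative, and 1305 had an unadjusted p under 0.05. Of the 10, 8 had the same sign in both dye assignments (2 positive, 6 negative), against 46.4% of all features tested. Quantile normalization left 7 calls (1 positive, 6 negative), of which 6 were among the 10. Those of Stmn1 (1.88) and Rgs4 (0.89) ended, though their ratios did not become smaller. Robust eBayes ended the call of Stmn1, loess correction those of Stmn1 and Rgs4, and the arrays with mutant RNA in Cy3 alone those of Rgs4 and the 5 named negative genes. With values in at least 2 litters none of the named cortex genes passed by limma (2 calls, 1645 features at an unadjusted p under 0.05). The calls depended on the litters. Without litter 1 limma called 0 features (1039 at an unadjusted p under 0.05), without litter 2 it called 1, without litter 3 it called 5 and without litter 4 it called 169 (110 positive, 59 negative), and the calls of Gja1, Sema7a, Hpca, Sncb, Cyria and Rgs4 ended without litter 1, 2 or 3, that of Stmn1 without litter 1 or 2 and that of Smtn without litter 1.

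Immature neuron genes in cortex had a mean log2 ratio of 0.23 (median 0.12), with 17 of 24 positive and 7 negative (camera adjusted p = 0.000264; adjusted p = 0.790 with an estimated correlation). Stmn1 passed over all features, and 5 positive genes passed adjusted over the list alone, among them Tubb3, a neuronal tubulin gene (0.54, adjusted p over all features 0.138), Cd24a, a surface protein of new neurons (0.59, 0.169), and Fabp7, a lipid carrier of radial glia (0.88, 0.261). The list mean was 0.0094 in the arrays with mutant RNA in Cy5 and 0.46 in those with control RNA in Cy5. Astrocyte genes had a mean of -0.13 (median -0.08), with 6 of 20 positive and 14 negative (camera adjusted p = 0.0188; adjusted p = 0.906 with an estimated correlation). Gja1 passed over all features, and 1 positive and 3 negative genes passed adjusted over the list alone. Among its members, Apoe had -0.60 (adjusted p over all features 0.211), Ndrg2 had -0.42 (0.218) and Id3 had 0.85 (0.193).

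Upper layer genes of the cortex had a mean log2 ratio of -0.11 (median -0.22), with 4 of 11 positive and 7 negative. Camera, on the 9 with values in all 4 litters (mean -0.15), gave an adjusted p of 0.0277, and of 0.823 with an estimated correlation. Layer 4 genes, which mark the layer where VB axons end, had a mean of -0.090 (median -0.055), with 6 of 12 positive and 6 negative. On the 9 with values in all 4 litters (mean -0.16), camera gave an adjusted p of 0.0393, and of 0.790 with an estimated correlation. In each of these lists 0 members passed over all features by limma, and 1 positive and 3 negative genes passed adjusted over the list alone. Members with the smallest p were Nr2f1, a transcription factor of area identity (-0.64, adjusted p over all features 0.131), the potassium channel gene Kcnh5 (-0.65, 0.158), Lmo4 (0.63, 0.190), Pou3f2 (-0.38, 0.289), Kitl (-0.37, 0.432) and Cux2 (-0.31, 0.452), and Lmo4 and Cux2 belong to both lists.

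Camera called 4 of 29 lists in cortex and 5 had an unadjusted p under 0.05. Camera with an estimated correlation called 0 and fry called 0 (with 0 and 2 lists at an unadjusted p under 0.05), and cameraPR called 2, immature neurons and astrocytes. The lost calls need not come from correlated genes. For layer 4 the estimated correlation was -0.014, below the preset 0.01, yet the unadjusted camera p went from 0.0054 to 0.063. Without litter 1 or 3 the astrocyte and immature neuron lists were called, and without litter 2 the upper layer and immature neuron lists. Without litter 4 the upper layer list alone was called. Calls without litters 1 to 4 thus numbered 2, 2, 2 and 1. Leaving out any 1 litter ended the call of the layer 4 list.

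Genes of barrel formation in cortex had a mean log2 ratio of -0.045, with 13 of 29 positive and 16 negative (camera adjusted p = 0.772, on 21 of them). Sema7a passed over all features, and 1 positive and 3 negative genes passed adjusted over the list alone. Of 9 RORα and clock genes, 3 were positive and 6 negative (mean -0.14), 0 passed over all features by limma, and 2 negative genes, Rora and the clock output gene Dbp (-0.44), passed adjusted over the list alone. Glutamate and GABA receptor genes had a mean of -0.076 over 23 genes (camera adjusted p = 0.0936, on 16 of them). Means of the other neuronal lists were -0.037 for deep layers, -0.017 for thalamic nuclei, 0.0086 for axon guidance, -0.010 for synaptic adhesion, 0.023 for activity-regulated genes, -0.035 for ion channels, -0.0070 for synaptic vesicles, -0.014 for neuronal maturation, -0.016 for GABAergic neurons and -0.063 for RORα targets of Purkinje cells. Lists of other cells had means of 0.032 for oligodendrocytes, -0.067 for microglia, -0.024 for vascular cells, -0.11 for blood cells, -0.0067 for choroid plexus and meninges and 0.022 for neighbouring regions. The remaining means were 0.040 for the cell cycle, 0.011 for cholesterol synthesis, -0.061 for glucocorticoid response, 0.052 for antioxidant genes, 0.013 for thyroid-responsive genes, 0.0063 for the neighbours of Rora and -0.11 for sex-linked genes. Among the last, Xist, expressed from the inactive X chromosome of females, had -0.78 ± 0.76 (SD, n = 3), did not pass over all features by limma and passed adjusted over the list alone, and without litter 4 it was called at -0.96 from 2 litters (limma adjusted p = 0.0487). The Y-linked genes Kdm5d (0.15), Uty (0.07) and Sry (0.05) did not pass. At least 1 member passed adjusted over the list alone in 18 of the 30 lists in cortex, against 14 of 30 in VB. Mean, median and camera direction differed in sign for 6 of the 29 lists, none of the 4 called.

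**Figure D3:**
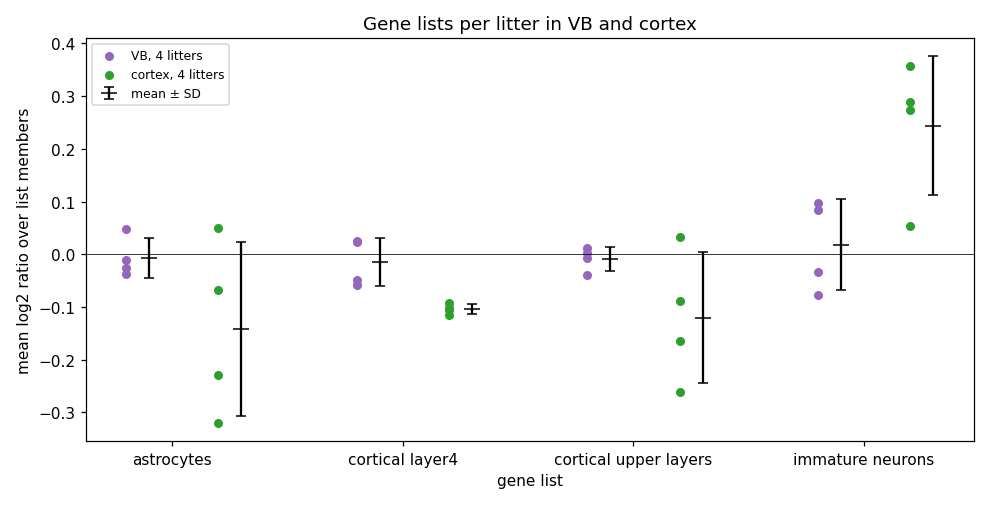
Mean log2 ratio over the members of the 4 lists called in cortex, for each litter (points), with mean and SD over litters (bars), in VB and in cortex. In cortex, layer 4 genes lay between -0.116 and -0.092 and immature neuron genes between 0.054 and 0.358. Astrocyte genes lay between -0.319 and 0.049 and upper layer genes between -0.262 and 0.033.

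The third comparison asked whether the ratios differed between VB and cortex. Ptges3, a cochaperone that makes prostaglandin E, had a VB minus cortex log2 ratio of 2.73 (2.54 in VB and -0.19 in cortex; limma adjusted p = 0.00059). Kif24 differed by 2.34 (1.28 and -1.06; adjusted p = 0.00059) and Cep152 by 1.77 (2.82-fold in VB and a log2 ratio of -0.27 in cortex; adjusted p = 0.0031). Slc25a1, the mitochondrial citrate carrier, differed by 1.37 (0.22 and -1.14; adjusted p = 0.0307), and the histone gene H3c14 by 1.03 (0.60 and -0.43; adjusted p = 0.0146). Smtn differed the other way, by -1.62 (-0.03 in VB and 1.59 in cortex; adjusted p = 0.0031).

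In all, 12 of 12179 features differed between the tissues, 10 with the VB ratio above the cortex ratio and 2 below it, and 1101 had an unadjusted p under 0.05. With litter as a replicate block 16 differed, 9 of them in both fits, and the call of Slc25a1 ended (adjusted p = 0.210). Loess correction brought Slc25a1 to 0.33 and H3c14 to 0.78, which ended both calls, and quantile normalization brought Slc25a1 to 2.25. With arrays kept apart the call of Smtn ended at -1.27. Only 1 of the 12 had the same sign in both dye assignments in each tissue, and it was none of the genes named above. Without litter 1 there was 1 call, without litter 2 there were 3, without litter 3 there were 4 and without litter 4 there were 14. The call of Kif24 ended without litter 1, that of Cep152 without litter 1 or 2, that of Smtn without litter 1 or 3, that of Slc25a1 without litter 1, 2 or 3 and that of H3c14 without any of the 4. Across the 12179 genes, which are not independent replicates, the mean ratios of VB and cortex had r = 0.0135 and rho = 0.0133 (exact p = 0.594 and 0.484 over 64 regroupings of the litters, of which 38 and 31 gave a value as large).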

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

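Every test of an explanation in this part was chosen after the result was seen, while the tests of the tissue difference and the comparison of litters were planned.

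Litter 4 lay far from the others for Ednrb in VB, at -0.36 against -0.89 to -0.81. Chance singles out about 1 in 20 groups, and this was 1 of 33 groups tested.

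A tested difference between VB and cortex singled out Ptges3 (2.73), Kif24 (2.34), Cep152 (1.77), Slc25a1 (1.37), H3c14 (1.03) and Smtn (-1.62). None of these had the same sign in both dye assignments in each tissue. Trim46 was positive in all 4 litters of VB and negative in all 4 of cortex, a distance of 1.02 (0.62 against -0.40; limma adjusted p of the difference 0.0208). For the 12 features that differed, 1 of 35 splits of the 8 litter values gave as many, the real one, and the highest other split gave 2. That share is under 0.05 only where the litters are taken as unpaired, so chance is not excluded. The labels give both tissues the same litters, and the splits that part all litter pairs number 8, of which 1 gave as many (real 12, highest other 0), too few for a share under 0.05. For the calls within a tissue the splits are too few as well. In VB 1 of 8 gave as many (real 51, highest other 2), in cortex 2 of 8 (real 10, highest other 12, from turning the sign of litter 4) and for the cortex lists 1 of 8 (real 4, highest other 1).

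The VB calls with opposite signs in the dye assignments form the first pattern. All 24 had a positive mean, from -0.90 with mutant RNA in Cy5 and 2.61 with control RNA in Cy5. Opposite signs as such were not particular to the calls, since 32.5% of all features tested in VB had the same sign. Dye bias left after averaging the swapped pair may account for part of the 24 but stays open. Quantile normalization left 4 of the 24 called against 14 of the 27 calls with the same sign (Fisher's exact p = 0.0176). That contrast mixes dye pattern with sign, since the 27 held 14 negative ratios and the 24 none. Every named positive VB ratio became smaller with quantile normalization, and every named negative one larger in size. The median ratio of the 24 went from 0.62 (SE 0.080) to 0.42 (SE 0.079), which still lay over 2 SE from 0. After loess correction it was 0.33 (SE 0.079), also over 2 SE from 0. Probes with no transcript in the tissue remain open, because receptors of the nose and tongue were 3 of the 24 (12.5%) against 4.13% of the features tested (Fisher's exact p = 0.0745), too few to decide. A genotype difference stays open too, since columns that follow the dyes would give it opposite signs in the dye assignments.

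Gja1, negative in both tissues if the columns run 1 way, forms the second pattern. With columns so turned, the highest orientation mean was -0.157, so Gja1 was negative in both assignments of both tissues. After loess correction it was -0.53 in VB (limma adjusted p = 0.0242) and -0.95 in cortex (limma adjusted p = 0.0183). These values argue against dye bias only in part. In VB the assignments still lay apart (-0.16 and -0.98), and the loess removes a trend shared across genes, not a bias of 1 probe. If the columns follow the dyes, a single sign in both assignments is what dye bias may give. The genotype ratio of Gja1 would then be 0.41 in VB and -0.22 in cortex. Dye bias therefore stays open. Over the alternatives that take the columns to run 1 way, the limma adjusted p ran from 0.0011 to 0.378 in VB and from 0.0014 to 0.112 in cortex. A different astrocyte share between the genotypes is argued against as the whole cause of the pattern as given, since the other 19 astrocyte genes had a median of -0.0564 (SD 0.286) in cortex and 0.0276 (SD 0.127) in VB. Gja1 was singled out for its ratio, so some distance from the other genes is built in. As part of the cause in cortex it stays open, since 14 of 20 astrocyte genes, Gja1 among them, were negative there (camera adjusted p = 0.0188, and 0.906 with an estimated correlation). A change of Gja1 itself may remain, as a hypothesis found and tested on the same data.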

How the results depend on the processing

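The restriction to genes with the same sign in both dye assignments, the loess dye correction, cameraPR and the Cy5 over Cy3 reading were chosen after seeing the data. In a tally that leaves out the Cy5 over Cy3 reading, named genes and lists other than Rora kept their sign and side of the threshold in 461 results under an alternative. Part of the 461 was fixed in advance. The fold of at least 1.5 gave 38 of them, but the tally did not apply the fold to named results. An adjusted p under 0.10, which cannot end a call, gave 37. Centring, on arrays with medians already between -0.003 and 0.004, gave 38. The named genes and lists kept the sign and lost the call in 166, gained it in 5 and reversed in 12. All 12 reversed in the arrays with mutant RNA in Cy5 alone, in VB Cep152 (-0.21), Cited4 (-2.72), Arhgef40 (-3.24), Kif24 (-0.037), Tcte3 (-0.97), Vmn1r219 (-0.99) and Trim46 (-0.66), in cortex Stmn1 (-0.14) and the immature neuron list (-0.0024), and between tissues Ptges3 (-0.46), Cep152 (-0.42) and H3c14 (-0.19). Those arrays gave 1170 calls in VB, 95 in cortex, 25 for the difference, 0 cortex lists (camera, 3 at an unadjusted p under 0.05) and a Rora ratio of 0.29 in VB, the reverse of -0.13. Arrays with mutant RNA in Cy3 alone gave 1677, 153, 453 and 1 cortex list, and Rora in VB passed at -0.56. Read as Cy5 over Cy3, Rora (0.42) and all genes named for the most positive or most negative ratios in VB would take the opposite sign. Among them were Iltifb (0.59), Calb2 (0.23) and Slc24a5 (-0.73), while in cortex some would keep it, as Gja1 (-0.22). Calls in VB numbered 19 with quantile normalization, 23 with loess correction, 83 with arrays kept apart, 20 with both tissues in 1 fit, 7 with values in at least 2 litters, 113 at an adjusted p under 0.10, 27 with the same sign in both assignments and 2785 read as Cy5 over Cy3 (1120 positive, 1665 negative, with 83 of 663 receptors of the nose and tongue). Calls in cortex numbered 46 with both tissues in 1 fit, 16 with each probe by itself, 6 with values in all 8 arrays, 2 with values in at least 2 litters, 22 at an adjusted p under 0.10 and 252 read as Cy5 over Cy3 (55 positive, 197 negative). The difference gave 21 with arrays kept apart, 3 with values in all 8 arrays, 0 with values in at least 2 litters (limma, 1998 at an unadjusted p under 0.05), 5 with loess correction and 16 with litter as a replicate block. Cortex lists numbered 2 with values in all 8 arrays, 0 with an estimated correlation (0 unadjusted), 0 by fry (2 unadjusted) and 2 by cameraPR. Leaving out 1 litter gave 32 to 156 calls in VB, 0 to 169 in cortex (0 without litter 1, by limma, with 1039 unadjusted), 1 to 14 for the difference and 1 to 2 cortex lists. The correlation between tissues ran from -0.018 without litter 3 to 0.031, and litters 1 and 2 in VB against 3 and 4 in cortex gave -0.0067. The cause was not tested. Without intensities, signal over background is unknown, and probes near background cannot be set apart.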

Other observations

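The genes named here and the tests of explanations for litter 4 were chosen after their values were seen, while leaving out each litter was planned.

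In cortex litters 1 to 3, without litter 4, limma called 169 features, 110 positive and 59 negative, and 151 of them had the same sign in both dye assignments (99 positive, 52 negative). Positive genes included Col5a3, a fibrillar collagen (2.13, adjusted p = 4.1e-07; litter 4 -0.42), Wdr6 (2.12, 8.8e-06; litter 4 -0.75) and Id3, an inhibitor of DNA binding in glia (1.15, 0.00022; litter 4 -0.07). Negative genes included Sncb (-1.02, 0.00042; litter 4 -0.58), the sodium pump subunit gene Atp1b1 (-0.93, 0.00085; litter 4 0.29), the scaffold gene Ank2 (-0.91, 0.0011; litter 4 -0.12), App, the amyloid precursor gene (-0.95, 0.0030; litter 4 0.03), and Hpca (-0.87, 0.0013; litter 4 -0.695). Litter 4 had a like value for some called genes, among them Gja1 (-0.79; litter 4 -1.36), Sema7a (-0.77; -1.05), Stmn1 (1.83; 1.59) and Mon2 (1.41; 1.16). Of 161 called features measured in litter 4, 77 had the same sign there (41 of 104 positive and 36 of 57 negative), 27 with at least 0.5 of the size, and 17 had the opposite sign with at least 0.5 of the size (binomial p = 0.174).

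That litter 4 of cortex stood apart from the others is the third pattern weighed, with the columns taken to run 1 way. Columns of litter 4 running the opposite way are argued against, because of the 200 genes with the smallest p in the other litters 98 had the same sign in litter 4 (binomial p = 0.832), where opposite columns would give few, and each of the other litters tested in this way gave 156, 154 and 140. For noisier arrays, the deviations of its swapped arrays had a rho of 0.128 against 0.0314, 0.0131 and 0.0576 in litters 1 to 3. These deviations were taken from a mean over all 4 litters. A litter that lacks a signal shared by the others would have a raised rho whatever its noise, so noisier arrays stay open. The slope of litter 4 on the mean of the others over the 200 genes was 0.0286, against 0.697, 0.521 and 0.423 for litters 1 to 3. In VB litter 4 also agreed least, but 135 of 200 genes had the same sign there (binomial p = 8.3e-07), against 166, 165 and 168. Its slope in VB was 0.360, against 0.844, 0.833 and 0.572. Noisier arrays, no genotype difference between the litter 4 RNAs, as a wrong label may give, and a biological difference of that litter could not be told apart. The genes that could tell them apart as a set went both ways in litter 4. Its means for the lists called in cortex were 0.290 for immature neurons, -0.230 for astrocytes, -0.106 for layer 4 and 0.0326 for upper layers. The last ran against the sign of its list. Litter 4 itself took part in calling these lists, so they cannot decide.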
